A study of Mus musculus with 2 samples.

How the data were processed

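H3K9me3, trimethylation of lysine 9 of histone H3, was measured by ChIP-seq (immunoprecipitation of fixed chromatin followed by sequencing) in mouse kidney at embryonic day 14.5. Per the labels, the tissue was pooled from healthy male and female embryos of B6N strains. There were 2 biological replicates from separate tissue samples. Replicate 1 had 1 technical replicate and replicate 2 had 2, which the authors combined. Library fragments were 300 to 500 bp long, per the labels. There was no second tissue, age or treatment, so the comparisons made were between the replicates, and between the peaks and chance placement along the genome.

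The authors called peaks on each replicate and on both replicates pooled, in each case against 2 control files, per the deposited file lists. They also derived a list of replicated peaks from the pooled list and the lists of both replicates. The 4 lists were in the narrowPeak format on mm10, per the labels. The aligner, the peak caller, their versions, their thresholds and the rule for a replicated peak are not given in the sources used here. The deposited signal value of a peak is its enrichment over control as the authors' peak caller gave it. The deposited lists also hold −log10 p-values and −log10 q-values per peak, and a display score that the authors scaled within each list and that was not used for any result. Signal, p and q are the authors' own values per peak, and were used only to describe, rank or filter peaks within a list. Control reads and aligned reads were not analysed here. The number of reads per library is therefore unknown, and a difference in the number of peaks between replicates cannot be separated from a difference in depth.

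Positions were read on the mouse reference of the same build (mm10, GRCm38), with GENCODE M21 genes, and are given 1-based. Peaks on chromosomes 1 to 19, X and Y entered all comparisons, and peaks on other scaffolds were counted separately. Overlap was at least 1 bp. The chance level came from 1000 circular shifts of all peaks along each chromosome, after gaps of at least 1000 unsequenced bases were taken out of the coordinates. A shift keeps the number, width and clustering of peaks. The smallest two-sided p that 1000 shifts can give is 0.001998. Alternatives for replicate overlap used 200 shifts (smallest p 0.00995), and sequence content used 100 (smallest p 0.0198).

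There were 20 gene lists, comprising gene families taken by symbol pattern, imprinted and germline genes, cell types of the kidney, cell types of other tissues, housekeeping genes and the enzymes and binding proteins of H3K9 methylation. For each list, the share of genes with a replicated peak in the gene body was compared with the shifts, and p-values were adjusted over the 20 lists by the Benjamini-Hochberg method. Symbols with more than 1 record were represented by the longest. 1 listed symbol, Hbb-b1, had no record, and 2 were matched by a synonym. The zinc finger list was taken by gene name, and its members were not checked for a KRAB domain. For position within genes, the body of each gene was divided into 3 equal parts along the direction of transcription. The share of its covered bases in each part was taken. List membership was permuted 100000 times among genes with a peak, two-sided (smallest p 1e-05). Promoters were within 1000 bp of a transcription start, and each peak midpoint was assigned to promoter, exon, intron or intergenic sequence in that order. The soft-masked part of the reference stood for repeats, since no repeat annotation was used.

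The rule for named genes took, for each list, up to 4 members with the most covered bases whose body was also overlapped in both replicates' own lists. It also took any covered imprinted gene or H3K9 methylation gene, and the 10 protein-coding genes outside all lists, of at least 2 kb, with the largest covered share. The 5 peaks of highest signal, the 5 widest regions after joining peaks within 1000 bp and the 5 windows of 1 Mb with the most covered bases were also taken. Design, lists, naming rule and most alternatives were chosen before the data were examined.

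Shares of peaks carry 95% Wilson intervals and density ratios carry exact binomial intervals, which cover counting error only. Alternatives included a −log10 q-value of at least 5, the pooled list, each replicate's own list, promoters only, flanks of 5 kb, a minimum of 500 covered bp, length-matched gene lists (10000 draws) and other rules of overlap. The gene list, gene part and overlap calculations were tested on simulated data. Of 200 simulated genes, 80 received a peak, and the share above chance came out at 31.3% against 33.3% put in. Of 100 lists without a planted effect, 3% had a permutation p below 0.05. The simulated overlap of 40% came out at 40.4%. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.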

Results

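H3K9me3, a histone mark of silenced chromatin, was mapped in the kidney of mouse embryos at day 14.5, when nephron progenitors, branching ureteric epithelium, stroma and early nephrons are present together. Each of the 2 biological replicates was a pool of embryos of both sexes. Replicate 1 had 36050 peaks covering 9.45 Mb, and replicate 2 had 50786 peaks covering 17.2 Mb. The median peak width was 217 bp in replicate 1 and 265 bp in replicate 2. A q-value below 0.05 was reached by 22.0% of replicate 1 peaks and 78.8% of replicate 2 peaks. The pooled list held 25750 peaks. The list of replicated peaks held 16599, all of them also in the pooled list, with a median width of 340 bp and a total of 7.13 Mb with scaffolds included. On the chromosomes they covered 0.262% of the sequence. Of the replicated peaks, 83.9% had a q-value below 0.05.

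The first comparison asked whether the replicates marked the same places. On the chromosomes, 13857 of 35757 replicate 1 peaks were overlapped by a replicate 2 peak (38.8%, 95% interval 38.2 to 39.3). In the other direction 13002 of 50539 replicate 2 peaks were overlapped (25.7%, 25.3 to 26.1). Strong peaks were shared more often than weak ones. In replicate 1 the overlapped share was 29.5% in the weakest of 5 equal classes by signal and 64.1% in the strongest, and in replicate 2 it was 14.5% and 49.8%. Chance overlap was 1.27% and 0.898%, so the observed shares were 30.5-fold and 28.6-fold higher (circular-shift permutation test, two-sided, p = 0.001998 for each, the smallest possible). The Jaccard index of covered bases was 0.151 against 0.00263 by chance (permutation p = 0.001998). Restricted to −log10 q-values of at least 5, the shares moved apart, to 76.0% of 467 replicate 1 peaks and 9.40% of 3617 replicate 2 peaks. The replicate 2 share is held down by the small number of replicate 1 peaks at this cutoff, whatever the agreement. With equal numbers of the strongest peaks by p-value (35757 in each replicate), the shares were 33.5% in replicate 1 and 30.6% in replicate 2.

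**Figure D1:**
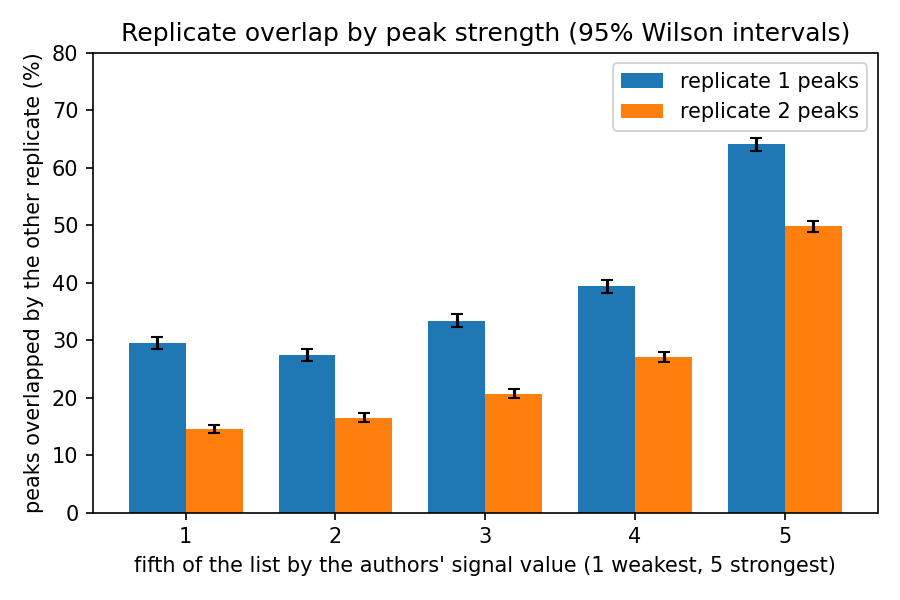
Share of each replicate's peaks overlapped by the other replicate (y axis, %) in 5 equal classes of the list by signal (x axis, 1 weakest to 5 strongest), with 95% Wilson intervals. The strongest class reaches 64.1% in replicate 1 and 49.8% in replicate 2.

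The replicated list leaned on replicate 2. Of its 16599 peaks, 15996 (96.4%, 96.1 to 96.6) were overlapped by replicate 2's own list and 12519 (75.4%, 74.8 to 76.1) by that of replicate 1. Both lists overlapped 11936 peaks (71.9%), replicate 2 alone 4060, replicate 1 alone 583 and neither 20.

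The next comparison asked where the mark lay along the genome. Chromosome 7, which holds many zinc finger and vomeronasal receptor genes, was the most densely marked, with 1811 replicated peaks or 12.8 per Mb. Chromosome 17 followed with 10.9 per Mb, and the autosomes together had 6.79 per Mb. Among peaks with −log10 q-values of at least 5, chromosome 17 was the densest at 1.11 per Mb. Chromosomes 18 (0.926) and 4 (0.868) were then also above chromosome 7 (0.839). Chromosome X had 121 peaks, 0.740 per Mb, which was 0.109 times the autosomal density (95% interval 0.0904 to 0.130). The ratio was 0.275 among peaks with −log10 q-values of at least 5, and 0.175 in replicate 2's own list, without replicate 1. Chromosome Y had 6 peaks. The densest 1 Mb window began at position 37000001 of chromosome 18 and covered the clustered protocadherin genes, with 131318 bp in 196 peaks. The next, from position 88000001 of chromosome 1, had 69339 bp over the Ugt1a and Mroh2a genes. Windows from position 82000001 of chromosome 10 (65754 bp, with Zfp873 and Zfp938) and from position 12000001 of chromosome 7 (58267 bp, with 9 zinc finger genes, among them Zfp110 and Zfp606) came after these. The last of the 5, from position 17000001 of chromosome 7, had 46035 bp over Ceacam and Psg genes, which encode cell adhesion molecules and pregnancy-specific glycoproteins.

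**Figure D2:**
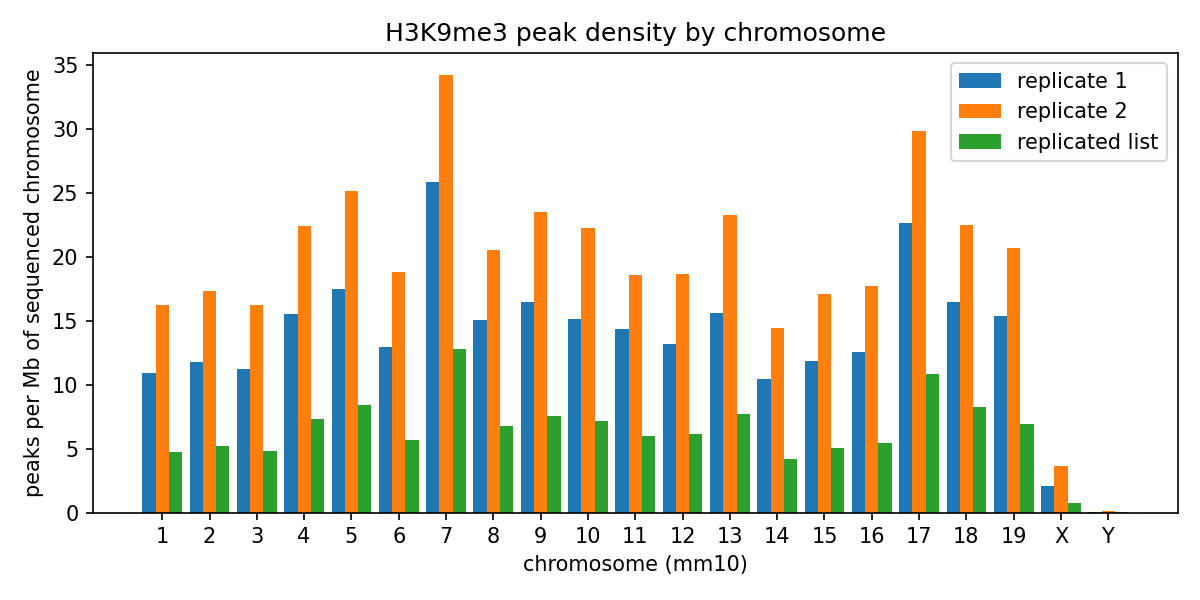
Peaks per Mb of sequenced chromosome (y axis) for chromosomes 1 to 19, X and Y of mm10 (x axis), in replicate 1, replicate 2 and the replicated list. In the replicated list chromosome 7 is highest at 12.8 and X is at 0.740.

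The peak of highest signal (12.2) was at chr6:30955648-30958712, over exon sequence of Klf14, a Krüppel-like transcription factor gene. On the chromosomes, the next 3 were at chr9:22278049-22281045 in an exon of Zfp810 (signal 9.84), at chr2:180642620-180644099 in an exon of Tcfl5 (9.55) and at chr14:118030791-118032285 in an intron of Dct (9.40). The widest joined region, chr1:88211390-88259779, spanned 48390 bp and held 22 peaks over the 3′ part of the Ugt1a cluster, whose genes encode glucuronosyltransferases, and over Mroh2a. Next came 45140 bp at chr18:37714631-37759770 and 24031 bp at chr18:37672921-37696951, both in the gamma protocadherins. A region at chr7:30147444-30167970 spanned 20527 bp over Gm10988 and Zfp146.

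By midpoint, 6.46% of replicated peaks lay in exons against 4.21% by chance, and 5.45% lay in promoters against 4.08%. The exon share was 14.3% among peaks with −log10 q-values of at least 5. Introns held 36.8% against 41.9% by chance. Each of these differed from the shifts with p = 0.001998 (permutation, two-sided). Intergenic sequence held 51.3% against 49.8% (permutation p = 0.186). Among peaks with −log10 q-values of at least 5 the intergenic share was 37.8%, below chance (permutation p = 0.001998), and the intron share of 40.7% did not differ from chance (permutation p = 0.651). Counted by gene, the promoters of protein-coding genes were not enriched. Replicated peaks overlapped 294 of 21938 of them, or 1.34% against 1.42% by chance (permutation p = 0.448).

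The central comparison asked which classes of genes carried the mark. Of 20 lists, 4 were covered more often than by chance and 0 less often: zinc finger genes, clustered protocadherins, imprinted genes and germline genes, each with an adjusted p of 0.00999. Where at least 500 bp of a gene had to be covered, the folds over chance were 5.04, 4.88, 6.66 and 3.91 in the same order. For these 4, in the longer lists of single replicates, the covered shares and the chance levels were higher and the folds were lower. Among all 21938 protein-coding genes, 3061 (14.0%) had a replicated peak, and the shifts gave 14.0%. With peaks of −log10 q-values of at least 5 the share was 2.48% against 1.88% by chance, and in replicate 2's own list it was 26.7% against 29.5% (permutation p = 0.001998 for each).

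Zinc finger genes, many of which encode DNA-binding repressors of transposable elements, were covered at 156 of 439 (35.5%), 2.83 times the chance level of 12.6%. The fold was 1.80 without replicate 1 (50.3% covered), 1.93 without replicate 2, and 10.6 with −log10 q-values of at least 5 (15.7% covered). Zfp873 (chr10:82048123-82064745) was covered over 12762 bp, or 76.8% of its body. Zfp110 on chromosome 7 was covered over 12481 bp (78.9%), Zfp68 on chromosome 5 over 11889 bp (73.8%) and Zfp930 on chromosome 8 over 11600 bp (54.0%). Chromosome 7 held 40 of the 156 covered genes. Zinc finger promoters were not enriched, with 8 of 439 covered (1.82%, adjusted permutation p = 1).

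Clustered protocadherins, cell surface proteins that give neurons distinct identities, were covered at 48 of 57 genes (84.2%), against 27.3% by chance, a 3.08-fold difference, which was 2.02-fold without replicate 1 (98.2%) and 2.14-fold without replicate 2. The clusters are neighbours on chromosome 18, and the central 95% of the shifts ran from 0% to 63.2%. The covered genes were 11 of 13 in the alpha cluster, 18 of 22 in the beta cluster and 19 of 22 in the gamma cluster. Gamma genes such as Pcdhga1 and Pcdhgb1 run to a shared 3′ end, so a peak can count for several of them. The gamma count is therefore not a count of separately marked genes. Pcdhga1 (chr18:37661793-37841873) had 80790 covered bp in 77 peaks, 44.9% of its body. Pcdhga2, Pcdhga3 and Pcdhgb1 had 77307, 73964 and 69362 covered bp, but these genes share most of their sequence with Pcdhga1 and are not independent observations. Their promoters were covered at 37 of 57 (64.9%, adjusted permutation p = 0.0133). With peaks of −log10 q-values of at least 5, 36.8% of the genes were covered against 3.48% by chance, a 10.6-fold difference, and the adjusted p was 0.230.

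Imprinted genes, expressed from the maternal or the paternal copy, were covered at 38 of 50 (76.0%) against 20.1% by chance, a 3.78-fold difference. It was 2.33-fold without replicate 1, 2.45-fold without replicate 2 and 16.9-fold with −log10 q-values of at least 5 (46.0% covered). The most covered bases lay in Gnas (10632 bp), Grb10 (7359 bp), Mest (6406 bp) and the antisense transcript Airn (5555 bp). The Airn peak at chr17:12741123-12743557 also lay within Igf2r. Other pairs shared their strongest peak in the same way, among them Gnas and Nespas, Blcap and Nnat, and Kcnq1 and Kcnq1ot1. Trappc9 and Peg13, and Snrpn and Snurf, did so too. The 38 covered genes are therefore not 38 separate loci. Peg3, a paternally expressed zinc finger gene, had 1 peak at chr7:6727484-6730754 reaching its 5′ end, with 2948 covered bp. Covered shares of the gene body were 76.1% in Cdkn1c, which encodes a cell cycle inhibitor, 64.2% in Nnat and 50.5% in Zrsr1. Meg3, a maternally expressed noncoding RNA, had 1555 covered bp in 3 peaks. Mcts2 was covered over 388 bp with 0 bp in replicate 1's own list. Imprinted promoters were covered at 20 of 50 (40%, adjusted permutation p = 0.0133).

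Germline genes, which act in germ cells and meiosis, were covered at 17 of 47 (36.2%) against 13.4% by chance, a 2.70-fold difference, which was 1.70-fold without replicate 1 (53.2% against 31.2%) and 1.91-fold without replicate 2. The largest coverage was in Meioc (1261 bp), a meiosis gene, in Piwil1 (906 bp) and Tdrd1 (834 bp) of the piRNA pathway, and in Ddx4 (857 bp), which encodes a germ cell RNA helicase. The Ddx4 peak spanned the 5′ end of the gene (chr13:112651619-112652749). Promoters were covered at 11 of 47 (23.4%, adjusted permutation p = 0.0133). With peaks of −log10 q-values of at least 5 the list was covered at 8.51% against 1.45% by chance, a 5.87-fold difference, and its adjusted p was 0.0666.

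Vomeronasal receptors, the pheromone receptors of sensory neurons, were covered at 54 of 327 (16.5%) against 9.24% by chance, with a permutation p of 0.0140 and an adjusted p of 0.0559. Vmn2r60 had 2846 covered bp and Vmn1r71 had 1563, both on chromosome 7. The call rested on the setting, since the adjusted p was 0.0160 with the pooled list and without replicate 2 (26.9% covered), and 1 without chromosome 7, where 12.1% were covered. Olfactory receptors were covered at 34 of 1106 (3.07%) against 4.01% by chance (adjusted permutation p = 1), and at 8.86% against 10.6% without replicate 1, with Olfr398 the most covered (1675 bp).

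Kidney lists did not differ from chance (adjusted permutation p = 1 for each). Nephron progenitor and early nephron genes were covered at 3 of 27, with Notch2 at 1011 bp. Ureteric bud and collecting duct genes were covered at 2 of 21, with Gfra1, a co-receptor for the branching signal Gdnf, at 1857 bp. Mature nephron genes were covered at 3 of 21, among them the podocyte gene Ptpro (646 bp) and the proximal tubule receptor Lrp2 (305 bp). Stromal genes were covered at 2 of 14, namely Fat4 (853 bp) and Pdgfrb (706 bp). These peaks were small parts of long genes, 0.843% of the body in Gfra1 and 0.739% in Notch2. The counts rested on the list used. Without replicate 1 they were 9, 5, 7 and 6 in the same order and without replicate 2 they were 7, 3, 8 and 2, with chance levels also higher and an adjusted permutation p of at least 0.234. In these 4 kidney lists 0% of promoters were covered, where chance gave 1.25% to 1.43% (adjusted permutation p = 1 for each). At these list sizes and chance levels a share of 0% could not be told apart from chance.

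Lists of other cell types also stayed within chance (adjusted permutation p = 1 for each). Endothelial genes were covered at 4 of 10, with Flt1 at 1373 bp, and the shifts gave 26.9%. They were covered at 6 of 10 without replicate 1, at 8 of 10 without replicate 2 (47.1% by chance, adjusted permutation p = 0.180) and at 2 of 10 with only peaks found in both replicates' own lists. Neural genes were covered at 2 of 19 (Syt1 and Rbfox3), liver genes at 2 of 14 (Cyp3a11 and Cps1), blood genes at 0 of 15 and muscle genes at 0 of 15. Genes of the 2-cell stage were covered at 2 of 22 (Obox6 and Pramef6). Housekeeping genes were covered at 1 of 20 (Tbp), and genes of H3K9 methylation at 2 of 24. These were Fam208a, a subunit of the HUSH silencing complex, and Setdb1, an H3K9 methyltransferase gene with 0 bp in replicate 1's own list. The methylation genes were covered at 6 of 24 without replicate 1, 5 without replicate 2 and 0 with only peaks in both lists, and the neural genes at 4 of 19 when either replicate was left out. Muscle genes were covered at 3 of 15 without replicate 1 (21.0% by chance) and 2 of 15 without replicate 2 (18.8% by chance). Blood genes were covered at 0 of 15 and 1 of 15 in the same order. Hox genes were covered at 0 of 39 and clustered histone genes at 0 of 71, where chance gave 3.91% and 1.22%. At these chance levels a count of 0 was not below what the shifts gave (permutation p = 0.591 and p = 0.987).

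**Figure D3:**
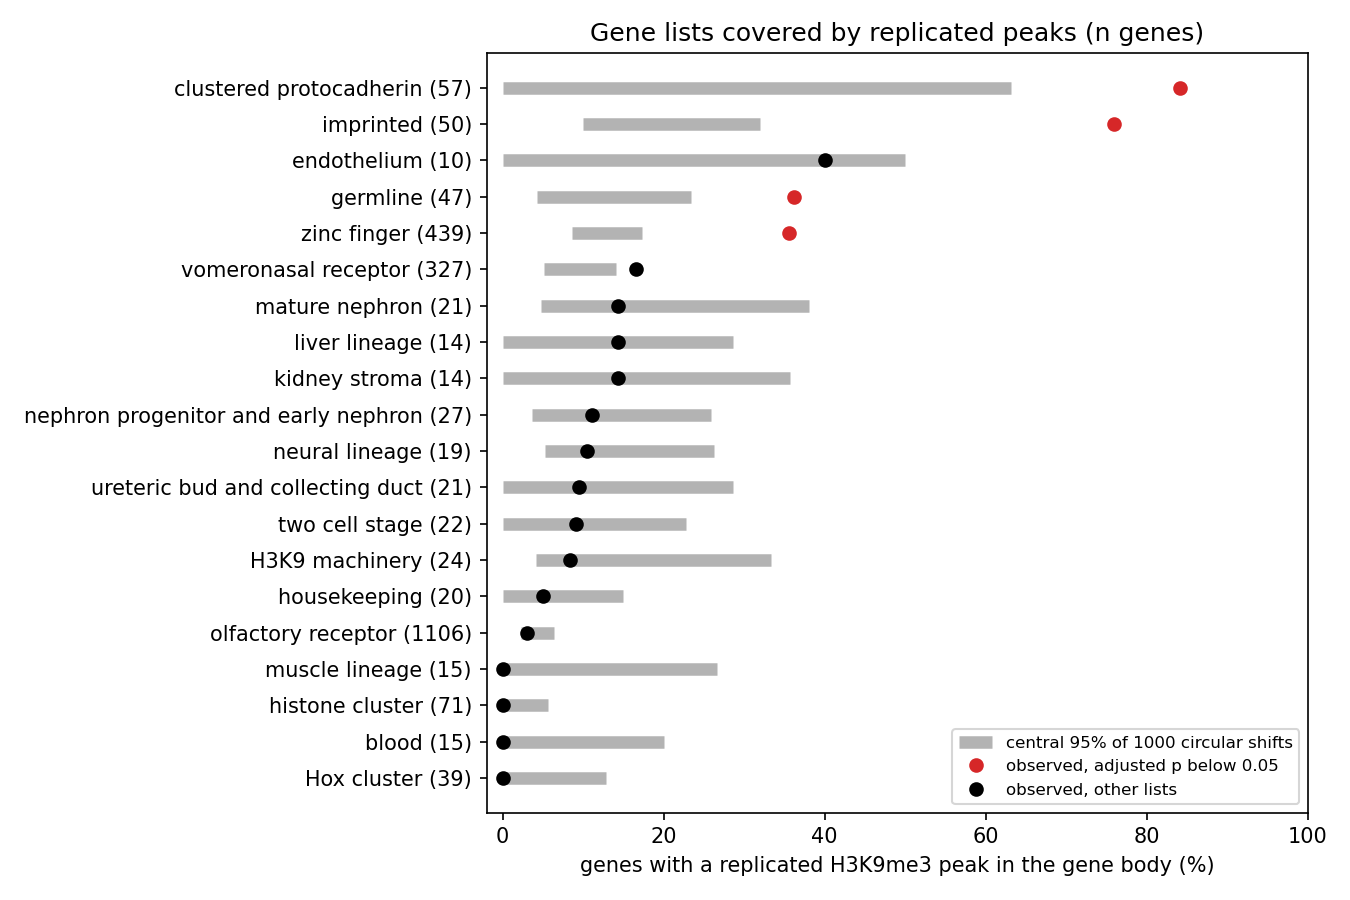
Share of genes with a replicated peak in the gene body (x axis, %) for the 20 lists (y axis, number of genes in brackets), as points, with grey bars for the central 95% of 1000 circular shifts. The protocadherin (84.2%), imprinted (76.0%), germline (36.2%) and zinc finger (35.5%) lists, in red, have adjusted p-values below 0.05.

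Outside the lists, among protein-coding genes of at least 2 kb, the largest covered shares were in Ugt1a1 (92.2%), Klf14 (88.0%) and Il3ra (86.2%). Gm21738 (85.1%), Asmt (84.1%) and Mroh2a (83.4%, 29451 bp) followed. Asmt, which encodes the last enzyme of melatonin synthesis, lay near the end of chromosome X at chrX:170672644-170678054. D1Pas1 (66.7%), Map10 (63.2%), AU022751 (62.0%) and Tmem185b (50.4%) completed the 10. In Gm21738, Ugt1a1 and Mroh2a the strongest peaks had modest signal (2.99, 4.21 and 5.06) for their −log10 q-values (41.5, 22.3 and 27.8). At Olfr398 a signal of 4.21 came with a −log10 q-value of 4.20. Control coverage was not examined, and regions of high control signal were not filtered out here. These genes, and the widest region and second densest window over Ugt1a1 and Mroh2a, may therefore not reflect the mark alone.

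A comparison of position within genes followed from the known placement of this mark over the 3′ exons of zinc finger genes. In the 156 covered zinc finger genes, the last of 3 equal parts of the body, at the 3′ end, held 61.2% of covered bases on average (SD 40.8), the middle part 23.3% and the 5′ part 15.5%. In the 4101 other covered genes the shares were 31.8% (SD 41.9), 33.3% and 34.9% in the same order. These other genes were not limited to protein-coding ones. The 3′ share differed by 29.4 percentage points (permutation test over genes, two-sided, p = 1e-05, the smallest possible). Genes of one cluster are neighbours and not fully independent, so this p describes genes, not separate clusters.

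**Figure D4:**
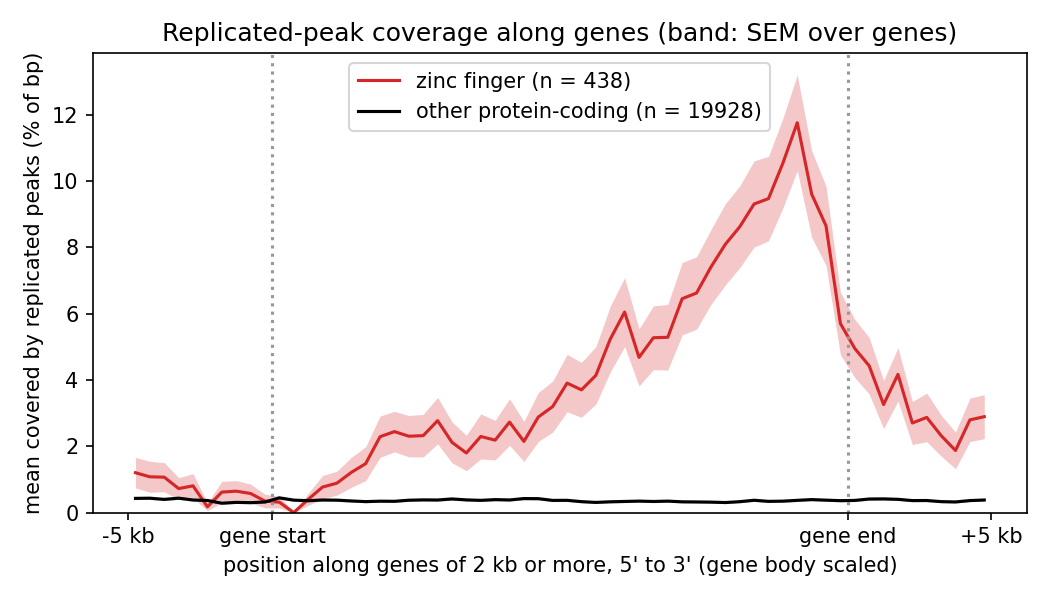
Mean share of bases covered by replicated peaks (y axis, %) along genes of at least 2 kb, scaled from start to end with 5 kb on both sides (x axis), for zinc finger genes (n = 438) and other protein-coding genes (n = 19928), with bands of 1 SEM over genes. In zinc finger genes coverage rises towards the 3′ end, to 11.8%, and is low at the gene start.

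The sequence under replicated peaks was compared with the same widths at shifted places. Soft-masked sequence, which marks repeats, made up 27.0% of peaks against 33.6% by chance. GC content was higher, at 45.8% against 42.1%. The ratio of observed to expected CpG was 0.212 against 0.193 (permutation of peak positions, two-sided, p = 0.0198 for each, the smallest possible). Shifted places include repeats where reads may map to several places, and reads were not analysed here. The lower soft-masked share therefore cannot be told apart from loss of such reads. The CpG difference depended on the list, with 0.192 in replicate 2's own peaks (permutation p = 0.554) and 0.294 in replicated peaks with −log10 q-values of at least 5.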

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

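The scaling of q-values on X and the comparison of flank and interior of proviruses were chosen only after the density on X and the coverage near primer-binding sites had been seen.

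Peaks also lay on unplaced and unlocalised scaffolds, which entered none of the comparisons with chance placement; the counts of replicated peaks overlapped by each replicate's own list include them. There were 209 in the replicated list, 293 in replicate 1 and 247 in replicate 2, or 39.2, 54.9 and 46.3 per Mb of the 5.33 Mb of scaffolds. On the chromosomes the densities were 6.19, 13.5 and 19.09 per Mb in the same order. The second strongest replicated peak (signal 11.2) and a joined region of 21116 bp were on scaffolds. Control coverage was not examined on scaffolds either, so these densities and peaks may not reflect the mark alone.

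The first pattern weighed was the low density on chromosome X, at 0.109 times that of the autosomes, or 0.175 without replicate 1. Zinc finger clusters on the autosomes did not account for it, since the ratio stayed at 0.109 (0.0894 to 0.131) with all sequence within 100 kb of zinc finger genes left out. In 1 Mb windows matched on soft-masked share the ratio was 0.0605 (0.0490 to 0.0738), which argued against soft-masked share as the whole cause. X windows were 46.8% soft-masked against 33.4% on autosomes, and the matching autosomal windows were few in the most masked class (28). Soft-masked share does not measure how many reads map to several places, so repeats that hide peaks by loss of such reads were not excluded. Lower copy number in a pool of both sexes was argued against as the whole cause by a ratio of 0.275 (0.180 to 0.401) among peaks with −log10 q-values of at least 5, below the bound of 0.5 set in advance; multiplying every autosomal −log10 q by 0.75, near the X copy number of an even pool, would leave a share of 0.520 of those peaks, but multiplying by 0.5 would leave 0.181, so a mostly male pool was not excluded, as its sex proportions are not given in the sources used here. No biological explanation was tested, since the design has 1 group.

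The second pattern was coverage near primer-binding sites, the 18 bp where a transfer RNA primes reverse transcription of a retrovirus. Replicated peaks lay within 1 kb of 43 of 174 exact proline sites (24.7%, 25.1-fold over chance), 20 of 67 lysine 1,2 sites (29.9%, 21.5-fold), 13 of 62 lysine 3 sites (21.0%, 16.8-fold) and 160 of 1090 phenylalanine sites (14.7%, 11.2-fold), each with p = 0.001998, the smallest the shifts can give, which is consistent with the mark on proviruses. Between 0.5 and 2 kb from the sites, 4.33% of bases were covered upstream, in the flank, and 0.761% downstream, inside the provirus, a ratio of 5.69 (bootstrap interval 3.86 to 9.90), but the difference was limited to short distances, with 0.509% upstream and 0.527% downstream at 2 to 5 kb (ratio 0.965) and 0.307% and 0.565% at 5 to 10 kb (ratio 0.543). Loss of reads that map to several places may hide part of the mark near the sites inside proviruses, although a mark that is truly lower there would give the same values, and no biological explanation was tested for the difference.

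The third pattern was the replicated peaks that replicate 1's own list did not overlap. Peaks of low signal were overrepresented, with 32.7% unsupported in the weakest of 5 equal classes and 9.12% in the strongest, a ratio of 3.59. All replicated peaks are also in the pooled list, whose signal includes replicate 1. A peak that is weak in replicate 1 thus tends to have a lower signal. The ratio therefore cannot decide whether limited strength accounts for the unsupported peaks. Unsupported peaks were 28.2% soft-masked and supported ones 26.6%. The difference of 1.65 percentage points argued against soft-masked share as the whole cause. Soft-masked share does not measure how many reads map to several places, so repeats that hide peaks by loss of such reads were not excluded. A lower read number in replicate 1 stays open, as reads were not analysed here. No biological explanation was tested.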

How the results depend on the processing

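The list of replicated peaks overlapped in both replicates' own lists, the omission of chromosome 7 and the omission of zinc finger members from other lists were chosen only after the data had been seen. Of 345 values over 39 results, 324 kept their side of the threshold or stayed in their interval. In 27 of these the value crossed to the other side of chance, past the threshold in neither setting. Of the rest, 7 moved out of their interval or count, 7 passed the threshold, 4 lost it, 2 passed it on the other side of chance and 1, a CpG ratio, lost it there. The cause was not tested except where stated. The overlap of replicates stayed above chance under all 8 alternatives, with the replicate 1 share between 18.5% and 76.0%. By p-value in place of signal, the overlapped share was 25.5% in the weakest class of replicate 1 and 13.01% and 51.3% in the weakest and strongest of replicate 2. With promoters only, zinc finger genes were covered at 1.82% (adjusted permutation p = 1). In covered zinc finger genes the 3′ part of the body held 61.2% of covered bases on average. Whether this placement accounts for the low promoter share was not tested.

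With −log10 q-values of at least 5, the number of lists above chance fell to 2, protocadherins being at 36.8% (adjusted permutation p = 0.230) and germline genes at 8.51% (0.0666), although their folds over chance rose to 10.6 and 5.87. All protein-coding genes turned above chance, at 2.48% (permutation p = 0.001998), and were at 26.2% to 26.7% when either replicate was left out, below chance without replicate 1 (permutation p = 0.001998). With the same q-value minimum, introns held 40.7% (permutation p = 0.651), intergenic sequence turned below chance at 37.8% (p = 0.001998), and the X to autosome ratio was 0.275. Intergenic shares above chance were 52.3% in the pooled list (permutation p = 0.0120) and 51.4% to 54.5% when either replicate was left out. Leaving out either replicate gave an X to autosome ratio of 0.141 to 0.175 and a CpG ratio of 0.192 to 0.203, the lower value, without replicate 1, not differing from chance (permutation p = 0.554). Vomeronasal receptors passed the threshold with the pooled list (21.4%, adjusted permutation p = 0.0160), without replicate 2 (26.9%, 0.0160; 25.7%, 0.394 without replicate 1) and against length-matched lists (16.5%, 8e-04). The 3′ bias of zinc finger genes held in all 6 alternatives, at 20.9 to 32.3 percentage points. What depth limits was not measured, since reads per library are unknown; 467 peaks of replicate 1 on the chromosomes reached a −log10 q-value of 5.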

Other observations

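The test of single-exon genes was chosen only after the genes with the largest covered share had been seen, and the members named here were chosen after their values were seen.

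Among the 12 imprinted genes without a replicated peak in the body, H19, Igf2 and Nap1l5 gained one when 5 kb on both sides were included, while Dlk1, Rasgrf1 and Ndn did not. All 30 germline genes without a peak, among them Dppa3, Stra8, Sohlh1 and Zp3, still had none with 5 kb of flank. In the protocadherin clusters, the genes without a peak included Pcdhac1, Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, the C-type members at the 3′ ends of the alpha and gamma clusters. Zinc finger genes were covered at 15 of 20 on chromosome 9, 17 of 46 on chromosome 13, 15 of 46 on chromosome 17, 2 of 8 on X and 0 of 4 on chromosome 3.

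Of the 10 most covered genes of at least 2 kb outside the lists, 3 had a single exon. With those 10 genes left out, 31 of 1053 single-exon protein-coding genes outside the lists had a replicated peak (2.94%) against 1.08% by chance, a 2.72-fold difference (permutation by circular shifts, p = 0.001998). Multi-exon protein-coding genes outside the lists, which are longer targets, were covered at 2663 of 18574 (14.3%), 0.930 times chance; the 2 groups were not compared directly. With at least 500 bp covered there were 9 single-exon genes (0.855% against 0.232% by chance, permutation p = 0.00999): Pkdrej (2193 bp), Rbmxl2 (1351 bp), Kbtbd7 (1287 bp), Slc25a2 (1242 bp), Galnt4 (876 bp), Ccer1 (666 bp), Cstf2t (635 bp), Pdha2 (539 bp) and Pabpc2 (507 bp). The Pabpc2 peak was not overlapped in both replicates' own lists, and Slc25a2 lies inside the protocadherin cluster. That single-exon genes may carry the mark more often than their placement by chance would give, at 2.72-fold, is a hypothesis found and tested on the same data.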
